A study of Mus musculus with 4 samples.

How the data were processed

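RNA of glial progenitors derived from mouse neural stem cells of the embryonic cerebral cortex (strain C57BL/6, wild type or Qk knockout) was selected for poly(A), made into libraries and sequenced on the Ion Proton System, per the labels' protocols. The authors deposited TPM per gene, a share of all transcripts, 1 table per library, with Entrez gene number and symbol, and each table sums to 1000000 within rounding. STAR 2.4.1d and RSEM 1.3.0 are named with mouse builds mm10 and GRCm38.p4 in the submitters' processing notes. The gene annotation, read filters, strand setting and read depth are not given in the sources used here. TPM keeps no depth, so no precision from read number can be stated, and the precision given here is the spread between libraries. Because TPM is a share of a total, a rise of abundant genes lowers all others.

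Libraries were grouped by the labels as 2 control and 2 Qk_KO, and all 4 entered 1 fit. Values were taken as log2(TPM + 1), that is with a pseudocount of 1. The 13260 of 35857 genes with a mean of at least 1 TPM over the 4 libraries were tested for Qk_KO minus control with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The moderated test had 5.57 degrees of freedom. An exact permutation test of 2 against 2 libraries has a share of 33.3% for complete separation and cannot pass that threshold, so p-values rest on limma's pooling of the spread across genes. Fold changes understate the change of low genes because of the pseudocount, and no fold is given against a group listed at 0. The symbol Plin2 was listed for 2 gene numbers, and genes were kept apart by number. Means are given with SD over the 2 libraries of a group.

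Before the data were examined, 27 gene lists were fixed: astrocyte, oligodendrocyte lineage, neural stem cell and radial glia, neurogenic progenitor, neuron, DNA replication and S phase, mitosis and G2/M, cholesterol synthesis, Notch pathway, BMP and JAK-STAT response, Sonic hedgehog and Wnt response, extracellular matrix and integrin, neural cell adhesion and axon guidance, RNA-binding proteins of neural splicing, literature Quaking targets, interferon response, p53 response, stress and unfolded protein response, immediate early, glycolysis and hypoxia, cytosolic ribosomal proteins, mitochondrially encoded, microglia and macrophage, endothelial, pericyte with fibroblast and meninges, erythroid, and ependymal with choroid plexus genes. Of 788 entries, 772 were matched by symbol or synonym, and the rest were not analysed here. The 24 lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over lists, and also with an estimated correlation, on ranks, and by fry. With an estimated correlation camera takes its degrees of freedom from the 4 libraries, so that version has little power. Some genes are in 2 lists or more, so lists are not independent.

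The rule for named genes, also fixed before, took Qk, then the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap, leaving out predicted and unnamed loci. It also took up to 4 called members of each list by size of change, or the 2 with the highest mean TPM where none was called, and Khdrbs1, Khdrbs2, Khdrbs3, Sf1, Gfap, Olig2, Pdgfra, Tubb3 and Sox2 whatever their call. Because small RNA genes filled many places, the same rule without them was added after the values were seen, and 1 gene it took is not reported here. Further genes named in a list or in the closing section outside the rule were chosen after their values were seen.

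The fit was tested on simulated data for this comparison, with log-normal values around the real means of the 13260 genes, limma's estimated spread and 200 genes changed. It recovered 64% of 50 genes changed by 1 log2 unit, 68% of those changed by 1.5, 86% at 2 and 98% at 3. There were 10 false calls, and 0 calls when no gene was changed. Simulated genes varied independently and followed limma's own model of the spread. Genes of the real libraries vary together, so these are not error rates for the real data. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, limma without a trend or with robust settings, the replicate number as a block and leaving out each library. Leaving out small RNA genes (RefSeq biotype) and removing each library's loess trend on transcript GC content were added after seeing the data. Gene positions, transcript lengths, GC content and 3' UTR sequences came from GENCODE M21 annotation of GRCm38, where 12462 of the genes tested had an entry by Entrez number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.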

Results

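Messenger RNA was profiled in glial progenitors that mouse neural stem cells of the embryonic cerebral cortex had formed 24 hr after the onset of induced glial differentiation. The series held 4 libraries, 2 from control cells and 2 from cells labelled as knockout of Qk (Qk_KO), the gene of the RNA-binding protein Quaking. Each library listed TPM, abundance as a share of all transcripts, for 35857 genes, a unit that keeps no read depth, so the depth behind each value is unknown and no counting interval is given. Between 18846 and 19387 genes were above 0 TPM per library, and the 10 most abundant genes took between 5.50% and 6.13% of each total. Pearson's r of log2(TPM + 1) across the 13260 genes tested was 0.985 between the control libraries, 0.978 between the Qk_KO libraries and 0.951 to 0.973 between libraries of different groups. Nothing in the labels says that libraries of a group came from separate cultures. The p-values of single genes rest on the spread between these libraries, which limma pools in part across genes. That spread may therefore be partly technical. Xist was at 0.04 and 62.5 TPM in Qk_KO replicates 1 and 2, and the Y-linked gene Eif2s3y at 35.4 and 0 TPM. These 2 libraries were therefore not technical repeats of the same cells, and for the controls the question stays open.

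The comparison asked how knockout of Qk changed the transcriptome of cells on the way to glia. Qk itself was measured first. Its level was 208 and 215 TPM in the control libraries and 36.1 and 43.7 TPM in the Qk_KO libraries, that is 211 ± 4.87 against 39.9 ± 5.31 TPM (SD, n = 2 per group), or 18.9% of control. Qk (Entrez gene 19317) lies on chromosome 17 at 10202601 to 10319854 on the minus strand of GRCm38. The log2 fold change was -2.38 (SE 0.12) with an adjusted p of 0.00708 (limma, Benjamini-Hochberg), on the log2(TPM + 1) scale, which understates the change of low genes, and all 4 libraries lay on the side their labels give. A TPM per gene sums all exons, so it does not show which part of Qk was removed. The call of Qk expression was lost without control replicate 1 (adjusted p = 0.0554 by limma with Benjamini-Hochberg adjustment), without control replicate 2 (0.0772) and with no filter on low genes (0.108), with log2 fold changes between -2.41 and -2.36.

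In the Qk_KO libraries, genes of glial precursors and of stress responses were among those that fell, and genes of neurons, the water channel gene Aqp4 and genes of mitosis were among those that rose. Pdgfra, the receptor of oligodendrocyte precursors, fell from 44.5 ± 12.2 to 8.75 ± 4.77 TPM (SD, n = 2), and Slc1a3, the astrocyte glutamate transporter, fell from 387 ± 68.6 to 133 ± 23.6 TPM. Aqp4 rose from 4.35 ± 0.742 to 32.2 ± 4.13 TPM, and Ina, which encodes the neuronal intermediate filament internexin, rose from 23.0 ± 10.3 to 91.0 ± 12.2 TPM. Ccnb1, the mitotic cyclin, rose from 26.1 ± 4.62 to 53.1 ± 2.51 TPM. Gfap, Olig2 and Sox2 were not called.

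Of the 13260 genes with a mean of at least 1 TPM, 430 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 242 higher and 188 lower in Qk_KO, and 203 of them by at least 1 log2 unit. In all, 403 of the 430 were protein-coding. The 2 values of each group lay apart for 8107 of the genes tested, or 61.1%, where chance gives 33.3% on average. Genes vary together between libraries, so this excess is not a test over independent genes. The count of calls depended on the settings. It was 0 with no filter on low genes, where 4327 genes had an unadjusted p under 0.05 in limma, 41 without limma's trend and 649 at a mean of at least 5 TPM. It was 10 without control replicate 1, 4 without control replicate 2, 60 without Qk_KO replicate 1 and 148 without Qk_KO replicate 2. All of the 430 genes kept their sign under every setting that still tested them. For all 430, however, both Qk_KO values lay on the same side of both control values. Leaving out a library or changing the pseudocount, filter, trend or block could therefore not change a sign. Only the settings that rescale the values could have done so. With each library's trend on transcript GC content removed, an alternative chosen after seeing the data, 352 genes passed, 151 higher and 201 lower.

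**Figure D1:**
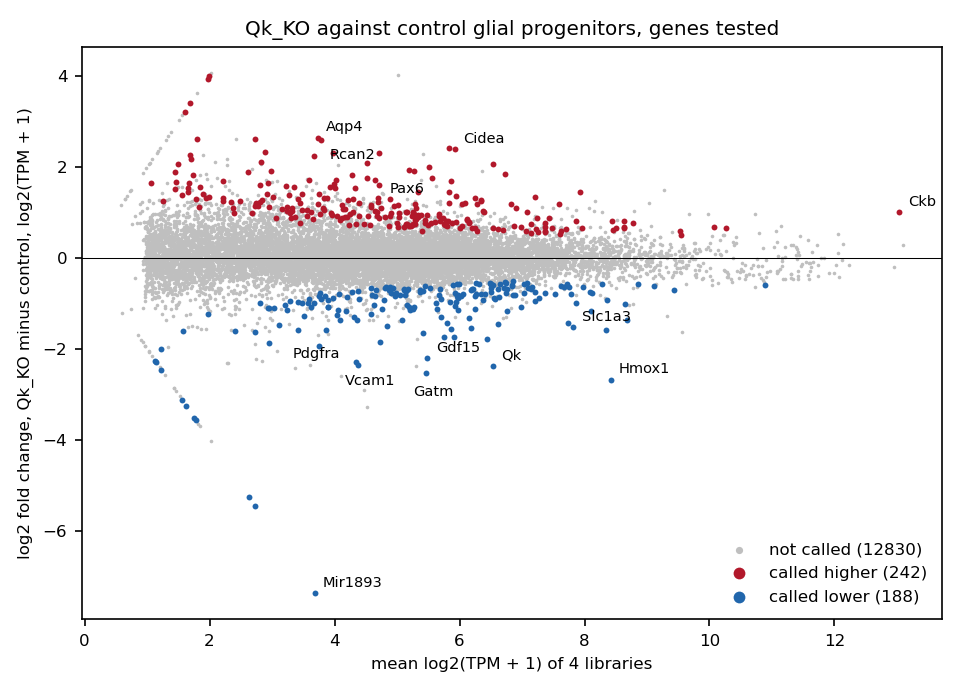
Each point is 1 of the 13260 genes tested, with the mean log2(TPM + 1) of the 4 libraries on the x axis and the log2 fold change of Qk_KO minus control on the y axis. The 242 genes called higher are red, the 188 called lower are blue and the rest are grey; the slanted edges at the left hold genes listed at 0 in one group, such as Mir1893.

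The fixed rule for named genes took the 10 largest increases and the 10 largest decreases among the calls. Small RNA genes filled many of these places. Mir6418, Mir697, Mir8115 and Snora70 were listed at 0 in both control libraries and at 19.5 and 11.4, 13.3 and 15.4, 12.9 and 6.86, and 10.7 and 6.29 TPM in Qk_KO replicates 1 and 2. Among the decreases, Mir1893 was listed at 370 and 72.5 TPM in the controls, Snord35a at 61.9 and 29.99, Mir3057 at 26.8 and 52.0, Snora44 at 18.6 and 6.21, Snora34 at 17.8 and 5.95, Mir6516 at 8.59 and 8.53, Snora2b at 7.79 and 7.75, and Snord15a at 4.44 and 4.57, and all of these were listed at 0 in both Qk_KO libraries. All 13 small RNA genes called, of 90 tested, had 1 group at 0. Among the small RNA genes listed at 0 in exactly 2 libraries, 13 of 23 (56.5%) had both in the same group, where chance gives 33.3%. Polyadenylated RNA was selected for these libraries, which such short transcripts largely lack, and with small RNA genes left out, an alternative chosen after seeing the data, 803 genes passed.

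The remaining places of the rule went to protein-coding genes. Aqp4 (chromosome 18, 15389496 to 15410982, minus strand, GRCm38) had a log2 fold change of 2.63 (SE 0.17, adjusted p = 0.0123 by limma with Benjamini-Hochberg adjustment). Cacng2, a subunit that traffics AMPA receptors, rose from 0.425 ± 0.375 to 7.92 ± 3.46 TPM (SD, n = 2), and Xkr7 rose from 1.89 ± 1.52 to 15.6 ± 3.39 TPM. Rcan2, an inhibitor of calcineurin, went from 4.65 ± 0.205 to 33.7 ± 10.6 TPM, Cidea, a lipid droplet protein, from 25.8 ± 5.67 to 138 ± 14.8 TPM, and Fndc1 from 2.32 ± 0.0566 to 15.8 ± 3.28 TPM. Hmox1, which encodes heme oxygenase (chromosome 8, 75093621 to 75100589, plus strand), fell from 878 ± 208 to 139 ± 52.99 TPM, a log2 fold change of -2.68 (SE 0.29, adjusted p = 0.0296 by limma with Benjamini-Hochberg adjustment). Gatm, an enzyme of creatine synthesis, fell from 108 ± 36.5 to 18.1 ± 7.80 TPM.

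The same rule with small RNA genes left out, applied after the values were seen, added Sez6l2, Actl6b, Iqsec3 and Kcnk1 to the increases, with log2 fold changes of 2.29, 2.29, 2.26 and 2.23. To the decreases it added Vcam1, an adhesion molecule, from 45.7 ± 0.446 to 8.17 ± 0.226 TPM (SD, n = 2), Gdf15, a stress-induced cytokine, from 95.4 ± 5.75 to 19.9 ± 1.01 TPM, and Pdgfra, Krt28, Layn, Flnc and Cav2.

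**Figure D2:**
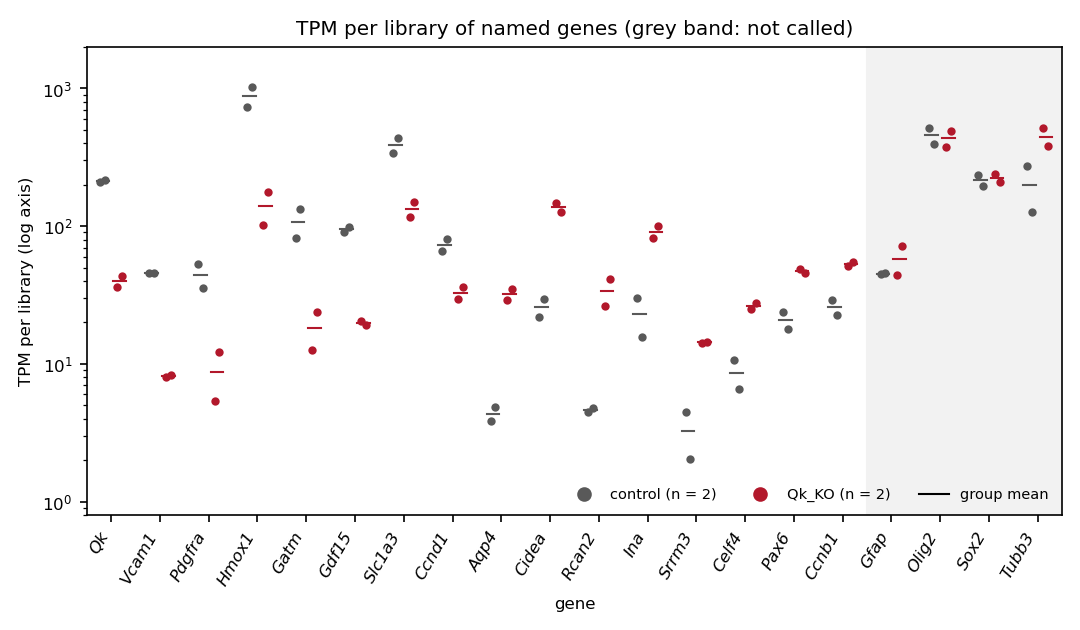
TPM per library on a log axis for 20 named genes, with control libraries in dark grey and Qk_KO libraries in red (n = 2 each) and a bar at each group mean. The 16 genes at the left were called, with Qk at 211 against 39.9 TPM, and Gfap, Olig2, Sox2 and Tubb3 in the grey band were not.

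Of the oligodendrocyte lineage list, 0 of 22 genes tested rose, 2 fell and 20 did not pass, and adjusted over the list alone 9 fell. Pdgfra and Lhfpl3 were the genes that fell, Lhfpl3 from 117 ± 0.509 to 69.5 ± 9.96 TPM (SD, n = 2). The list was called lower by camera in limma (median log2 fold change -0.75, Benjamini-Hochberg adjusted p = 4.6e-06), with 20 of 22 log2 fold changes below 0. This call was lost at an adjusted p = 0.719 with an estimated correlation. Both Qk_KO values lay below both control values for 14 of the 22 genes. Replicates of a group also differed: Mbp was at 11.0 and 47.3 TPM in control replicates 1 and 2, and at 3.58 and 11.1 TPM in Qk_KO replicates 1 and 2. Pdgfra ran the other way in the controls, at 53.1 and 35.8 TPM. Sox10, the lineage's transcription factor, stood at 29.0 ± 16.7 against 4.96 ± 3.66 TPM with an adjusted p of 0.0701 (limma, Benjamini-Hochberg). Olig2 stood at 458 ± 84.4 in control and 435 ± 81.6 TPM in Qk_KO. The microglia and macrophage list lay lower in the same libraries, with a median of -0.95.

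Members of the astrocyte list went both ways, with 2 of 30 higher, 3 lower and 25 not called, and 9 higher and 11 lower adjusted over the list alone. Aqp4 and Tnc, a matrix glycoprotein, rose, and Slc1a3, the bicarbonate transporter gene Slc4a4 and the proteoglycan gene Bcan fell. Tnc rose from 262 ± 7.85 to 456 ± 33.0 TPM and Slc4a4 fell from 31.7 ± 2.38 to 18.9 ± 0.955 TPM (SD, n = 2). Gfap, the astrocyte filament, was at 45.2 ± 0.204 in control and 58.1 ± 19.9 TPM in Qk_KO. The list was not called by camera (Benjamini-Hochberg adjusted p = 0.467). In the neural stem cell and radial glia list, 1 of 28 genes rose, 2 fell and 25 did not pass, and 2 rose and 4 fell adjusted over the list alone. Pax6, a transcription factor of cortical radial glia, rose from 21.0 ± 4.29 to 47.4 ± 2.21 TPM, while the endothelin receptor gene Ednrb fell from 415 ± 48.7 to 183 ± 11.9 TPM and Ptprz1 fell from 244 ± 22.6 to 157 ± 5.23 TPM. Sox2 was at 215 ± 27.6 and 224 ± 22.3 TPM.

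On the neuronal side, 4 of 34 genes of the neuron list rose, 0 fell and 30 did not pass, with 5 higher and 0 lower adjusted over the list alone. These 4 were Ina, the RNA-binding protein genes Celf4 and Celf3, and Snap25 of the synaptic vesicle fusion machinery. Celf4 rose from 8.63 ± 2.98 to 26.3 ± 1.68 TPM and Snap25 from 15.5 ± 3.78 to 34.5 ± 4.24 TPM (SD, n = 2). The list was called higher by camera in limma (median 0.50, Benjamini-Hochberg adjusted p = 0.0063, and adjusted p = 0.745 with an estimated correlation). Tubb3 was at 200 ± 105 in control and 448 ± 91.7 TPM in Qk_KO, with an adjusted p of 0.104 (limma, Benjamini-Hochberg). List members Dlx1 and Dlx2 were high in Qk_KO replicate 1 alone, at 36.7 and 76.0 TPM, against 0.40 and 1.70 TPM in Qk_KO replicate 2. The neurogenic progenitor list had 0 of 20 genes called, also adjusted over the list alone, with Tubb2b at 2524 ± 299 and 2885 ± 110 TPM and Sox4 at 352 ± 68.3 and 452 ± 6.48 TPM. Its camera p, adjusted by Benjamini-Hochberg in limma, was 0.177. It was 0.00231 without control replicate 1 and 0.00393 at a mean of at least 5 TPM, with medians of 0.57 and 0.44.

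In the RNA-binding proteins of neural splicing list, 4 of 34 genes rose, 0 fell and 30 did not pass, and the same counts held adjusted over the list alone. Srrm3, a neuronal splicing regulator, rose from 3.27 ± 1.75 to 14.3 ± 0.261 TPM and Rbfox2 from 36.0 ± 5.15 to 69.0 ± 6.98 TPM (SD, n = 2), next to Celf3 and Celf4. The list's camera p, adjusted by Benjamini-Hochberg in limma, was 0.144, and it was 0.0294 without control replicate 1 and 0.0106 with the GC trend removed. The other genes of Quaking's STAR family were not called. Khdrbs1 was at 166 ± 22.9 and 192 ± 3.05 TPM, Khdrbs2 at 17.6 ± 5.85 and 15.5 ± 3.51 TPM, Khdrbs3 at 108.1 ± 1.06 and 124 ± 1.39 TPM, and Sf1 at 169 ± 6.57 and 158 ± 2.77 TPM. The list of Quaking targets from the literature had 0 of 9 genes called, also adjusted over the list alone, with Hnrnpa1 at 854 ± 62.2 and 910 ± 24.3 TPM, Stat3 at 159 ± 11.9 and 176 ± 13.2 TPM, and a Benjamini-Hochberg adjusted camera p of 0.852.

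All 39 genes of the mitosis and G2/M list had positive log2 fold changes, 4 of them called over all genes, 0 lower and 35 not called, and 36 higher adjusted over the list alone. The kinesin gene Kif20a rose from 10.8 ± 3.11 to 25.0 ± 1.02 TPM and the checkpoint kinase gene Bub1b from 11.2 ± 2.24 to 24.6 ± 0.622 TPM (SD, n = 2), with the cyclin genes Ccnb1 and Ccnb2. The list was called higher by camera in limma (median 0.97, Benjamini-Hochberg adjusted p = 3.35e-15, and adjusted p = 0.719 with an estimated correlation). The estimated correlation of its genes was 0.782, above the preset one, so the smaller p does not measure the spread between libraries. The DNA replication and S phase list had 0 of 37 genes called, also adjusted over the list alone, with Pcna at 154 ± 3.03 and 209 ± 57.2 TPM and Rrm2 at 73.9 ± 28.6 and 120 ± 59.1 TPM. It too was called higher (median 0.65, Benjamini-Hochberg adjusted camera p = 6.19e-05, and adjusted p = 0.745 with an estimated correlation). Without Qk_KO replicate 1 its median was 0.24 and that call was lost (adjusted p = 0.159). Ccnd1, the cyclin of G1, fell from 73.3 ± 10.2 to 33.0 ± 4.75 TPM.

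In the Sonic hedgehog and Wnt response list 3 of 21 genes rose, 2 fell and 16 did not pass, and 6 rose and 4 fell adjusted over the list alone. Wnt7a rose from 31.8 ± 6.31 to 104 ± 13.6 TPM while Wnt7b fell from 26.2 ± 1.41 to 9.67 ± 1.64 TPM (SD, n = 2), Dkk3 and Nkd1 rose, and Ccnd1 fell. In the BMP and JAK-STAT response list 1 of 28 genes rose, 1 fell and 26 did not pass, with 3 higher and 2 lower adjusted over the list alone: Il6st, the shared receptor subunit of gliogenic cytokines, rose from 53.5 ± 5.12 to 93.1 ± 7.09 TPM, and Cebpd fell from 53.7 ± 5.43 to 20.5 ± 5.80 TPM. In the Notch pathway list 0 of 22 genes rose, 21 did not pass and the ligand gene Jag1 fell, from 17.1 ± 2.28 to 8.03 ± 0.353 TPM, with 3 higher and 1 lower adjusted over the list alone. Camera called none of these 3 lists, at Benjamini-Hochberg adjusted p of 0.852, 0.878 and 0.177, and the Notch list passed at 0.0446 without control replicate 1.

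The extracellular matrix and integrin list had 2 of 43 genes higher, 3 lower and 38 not called, with 5 higher and 10 lower adjusted over the list alone. Mmp14, a membrane-bound metalloprotease, rose from 57.5 ± 0.762 to 119 ± 24.2 TPM, as did Tnc, and the integrin gene Itgb8 fell from 55.7 ± 2.67 to 24.8 ± 1.15 TPM (SD, n = 2), as did Col11a1 and Bcan. Of the neural cell adhesion and axon guidance list 2 of 61 genes rose, Slit3 and Ephb1, 0 fell and 59 did not pass, with 5 higher and 1 lower adjusted over the list alone. Camera did not call either list (Benjamini-Hochberg adjusted p of 0.154 and 0.39 in limma). In the cholesterol synthesis list 1 of 24 genes rose, Ebp, 1 fell, Hmgcs1, and 22 did not pass, and adjusted over the list alone the counts were also 1 and 1. Its camera p, adjusted by Benjamini-Hochberg, was 0.852, but without Qk_KO replicate 1 the list was called higher (adjusted p = 0.0203) and without Qk_KO replicate 2 it was called lower (0.00303).

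Lists of stress genes were called lower in Qk_KO, alongside the microglia and macrophage list. The stress and unfolded protein response list had 0 of 25 genes higher, 1 lower, Hmox1, and 24 not called, with 10 lower adjusted over the list alone, and was called lower by camera in limma (median -0.38, Benjamini-Hochberg adjusted p = 6.19e-04, and adjusted p = 0.719 with an estimated correlation). The p53 response list had 0 of 24 genes higher, 1 lower, Gdf15, and 23 not called, with 2 higher and 4 lower adjusted over the list alone. It was called lower (median -0.28, Benjamini-Hochberg adjusted camera p = 0.00501, and adjusted p = 0.738 with an estimated correlation), a call lost without Qk_KO replicate 1 (adjusted p = 0.0814). In the immediate early list 1 of 20 genes rose, the phosphatase gene Dusp1, 0 fell and 19 did not pass, with 1 higher and 6 lower adjusted over the list alone. Its median was -0.25 with a Benjamini-Hochberg adjusted camera p of 0.0244 and an adjusted p = 0.719 with an estimated correlation, and the call was lost without control replicate 2 (0.0775), without Qk_KO replicate 1 (0.111) and at a mean of at least 5 TPM (0.0566).

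The cytosolic ribosomal protein list had 0 of 56 genes called over all genes and 26 lower adjusted over the list alone, with 55 of 56 log2 fold changes below 0. It was called lower by camera in limma (median -0.32, Benjamini-Hochberg adjusted p = 2.44e-13, and adjusted p = 0.719 with an estimated correlation). Rps2 was at 5073 ± 25.9 and 4539 ± 222 TPM and Rps18 at 4967 ± 425 and 3713 ± 121 TPM (SD, n = 2). In the glycolysis and hypoxia list Tpi1 and Pfkm, enzymes of glycolysis, rose, Adm, a hypoxia-induced peptide gene, fell and 19 of 22 did not pass, with 10 higher and 3 lower adjusted over the list alone. The median was 0.29 with a Benjamini-Hochberg adjusted camera p of 0.0244 and an adjusted p = 0.719 with an estimated correlation. This call was lost without control replicate 1 (0.142), without Qk_KO replicate 1 (0.122), with no filter (0.064) and with the GC trend removed (0.0631). Of the interferon response list 2 of 19 genes rose, Ifitm3 and Bst2, 0 fell and 17 did not pass, with 3 higher and 0 lower adjusted over the list alone. It was called higher (median 0.37, Benjamini-Hochberg adjusted camera p = 0.0134, and adjusted p = 0.719 with an estimated correlation), but not without control replicate 1 (0.055) or without Qk_KO replicate 1 (0.056).

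Lists of other cell types were also tested. All 13 genes tested of the microglia and macrophage list had lower values in both Qk_KO libraries than in both controls. Over all genes 0 passed (limma), and 11 were lower adjusted over the list alone. The list was called lower by camera in limma (median -0.95, Benjamini-Hochberg adjusted p = 3.85e-07, and adjusted p = 0.719 with an estimated correlation), with Lyz2 at 30.6 ± 2.47 and 15.1 ± 4.59 TPM and Tyrobp at 10.9 ± 1.42 and 4.38 ± 1.41 TPM (SD, n = 2). The endothelial list had 0 of 5 genes called and 1 lower adjusted over the list alone, with Itm2a at 24.5 ± 4.99 and 13.4 ± 0.431 TPM and Eng at 3.39 ± 0.191 and 4.005 ± 0.163 TPM. In the list of pericytes, fibroblasts and meninges Pdgfra alone of 12 genes fell, 11 did not pass, and 1 was lower adjusted over the list alone. Camera called neither list (Benjamini-Hochberg adjusted p of 0.878 and 0.282). Only 3 ependymal and choroid plexus genes could be tested, too few for camera, and Folr1 rose from 0.385 ± 0.0778 to 4.79 ± 1.22 TPM, also adjusted over the list alone. Of the erythroid list 11 of 12 genes were listed and 0 reached the filter. Mitochondrially encoded genes were not analysed here because no such symbol is among the genes listed.

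**Figure D3:**
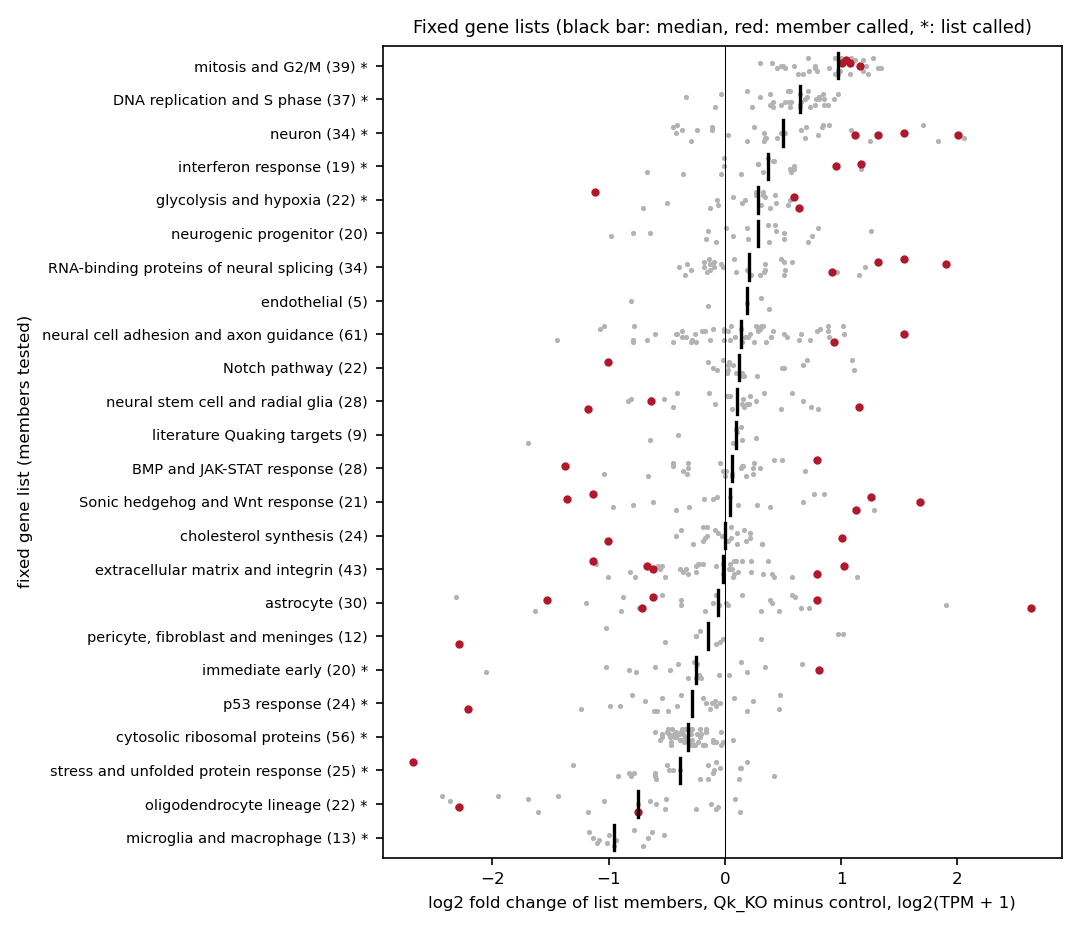
Log2 fold changes of Qk_KO minus control on the log2(TPM + 1) scale for the members of the 24 fixed lists with at least 5 genes tested, sorted by median (black bar). Red points are members called over all genes, grey points are not called, and an asterisk marks the 11 lists called by camera with a preset correlation, from mitosis and G2/M at a median of 0.97 to microglia and macrophage at -0.95.

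Of the 24 lists tested, camera with a preset correlation called 11, 5 higher and 6 lower, and 6 of these calls held when each library in turn was left out. With an estimated correlation camera called 0 lists, and 0 had an unadjusted p under 0.05. This version takes its degrees of freedom from the 4 libraries and has little power, so its lack of calls does not show that lists were unmoved. Estimated correlations of the 11 called lists ran from 0.0272 (glycolysis and hypoxia) to 0.945 (DNA replication and S phase), above the preset 0.01. They were 0.782 for the mitosis and G2/M list, 0.423 for the oligodendrocyte lineage list and 0.356 for the neuron list. Camera p-values with the preset correlation thus assume less shared variation than was estimated, and do not measure the spread between libraries. The self-contained test fry, whose p asks whether the genes of a list move on balance in one direction, called 0 lists after Benjamini-Hochberg adjustment, with 5 at an unadjusted p under 0.05.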

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

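The alternatives with small RNA genes left out and with the GC trend removed were chosen after seeing the data, and TPM rescaled without mitochondrially encoded genes was not run because no such symbol is listed. Qk expression had a log2 fold change of -2.38 with no filter (adjusted p = 0.108 by limma with Benjamini-Hochberg adjustment) and between -2.52 and -2.25 with each library left out, where the adjusted p was 0.0554 without control replicate 1 and 0.0772 without control replicate 2. Under its other alternatives Qk stayed called, at adjusted p between 0.00516 and 0.0322. The number of genes changed, 430, became 0 with no filter (4327 at an unadjusted p under 0.05 in limma), 649 at a mean of at least 5 TPM, 41 without a trend, 803 with small RNA genes left out and between 4 (without control replicate 2) and 148 with each library left out. Under pseudocounts of 0.1 and 0.5, median-ratio scaling, quantile normalization, robust settings and the GC trend removed it lay between 352 and 584. The number of lists called, 11, was 0 with an estimated correlation, between 7 (without Qk_KO replicate 1) and 12 with each library left out, and 10 or 11 otherwise. With a library left out, fewer samples remain, and the lone sample of a group is assumed to vary like the other group. Of 70 named genes called besides Qk, 70 lost the call with no filter, 52 without a trend, 13 with the GC trend removed, 5 with quantile normalization and 3 with robust settings, and only 1 kept it whichever library was left out (3 without control replicate 1, 2 without control replicate 2, 22 without Qk_KO replicate 1 and 27 without Qk_KO replicate 2 kept it). The cause was not tested.

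With the replicate number as a replicate block, 1278 genes were called, including all 430, and 6 named genes not called before, Tubb3, Rrm2, Rps18, Lyz2, Tyrobp and Itm2a, passed, although the deviations of libraries with the same number correlated at only 0.114 and the labels do not pair them.

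Results that changed sign were uncalled before. The cholesterol synthesis list had a median of -0.028 with median-ratio scaling, -0.011 with quantile normalization, -0.071 with the GC trend removed and between -0.19 and 0.21 with each library left out, called lower without Qk_KO replicate 2 and higher without Qk_KO replicate 1. The Sonic hedgehog and Wnt response list was at -0.0083 at a mean of at least 5 TPM and -0.11 with the GC trend removed. That setting also gave -0.014 for the neural stem cell and radial glia list, -0.0012 for the Notch pathway list and -0.023 for Sox2. With each library left out, the range was -0.040 to 0.18 for the neural stem cell and radial glia list, -0.013 to 0.15 for the BMP and JAK-STAT response list, -0.012 to 0.17 for the literature Quaking targets list, -0.48 to 0.17 for Khdrbs2, -0.27 to 0.12 for Olig2, -0.071 to 0.19 for Sox2 and -0.038 to 0.66 for Gfap. The cause was not tested. Read depth is unknown, so its limit on low genes cannot be given.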

Other observations

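The tests of a Quaking response element matched on 3' UTR length were planned before the result was seen. All other tests in this part, those also matched on GC content included, and the genes named in this paragraph and the next, were chosen after the results were seen. These genes were picked from the calls, belong to no fixed list and were not tested as groups, so they do not show that a family moved as a whole. Cav1, which encodes the main caveola protein, went from 568 ± 152 to 191 ± 61.4 TPM (SD, n = 2), Cav2 from 110.1 ± 23.9 to 32.3 ± 6.85 TPM and the coat gene Ptrf from 171 ± 27.1 to 98.7 ± 4.58 TPM. Of genes with a role in endosomes and traffic, Snx5 went from 124 ± 17.4 to 41.6 ± 2.23 TPM, Rab5a from 93.9 ± 12.5 to 41.4 ± 4.14 TPM, Vps35 from 134 ± 21.0 to 72.9 ± 3.22 TPM and Vamp3 from 101 ± 12.1 to 55.9 ± 3.74 TPM. The cytoskeletal regulators Rhoa and Msn fell from 455 ± 32.7 to 238 ± 2.23 TPM and from 327 ± 16.4 to 163 ± 2.01 TPM. Each of these passed limma with Benjamini-Hochberg adjustment, at adjusted p between 0.0210 and 0.0483.

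Other called genes, picked in the same way, were higher in Qk_KO. The granin genes Chga and Chgb went from 19.7 ± 7.45 to 74.1 ± 10.9 TPM and from 18.3 ± 6.30 to 70.7 ± 12.6 TPM (SD, n = 2). Cplx1, Syt7 and Stx1a of vesicle fusion rose to 45.6 ± 11.6, 33.1 ± 4.35 and 31.1 ± 0.658 TPM, from 14.1 ± 0.530, 10.9 ± 2.04 and 15.9 ± 0.340 TPM. The receptor subunit genes Gabrb1, Gabra4 and Gabbr2 had log2 fold changes of 1.83, 1.67 and 1.41 (adjusted p of 0.0286, 0.0424 and 0.0336 by limma with Benjamini-Hochberg adjustment), although Gabrb1 and Gabra4 reached only 5.28 ± 0.247 and 3.93 ± 0.714 TPM. Ckb, brain creatine kinase, was the most abundant gene of both Qk_KO libraries and rose from 5981 ± 723 to 11905 ± 1122 TPM.

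Quaking binds RNA at a response element made of an ACUAAY core with a UAAY site nearby, and one hypothesis is that loss of binding lowers its targets. An element was present in the longest annotated 3' UTR of 61 of the 168 genes that fell and have such a UTR, leaving out Qk, or 36.3%. The share was 14.9% in uncalled genes matched on 3' UTR length (middle 95% of 10000 draws 10.1% to 20.2%). The two-sided matched-draw p was 1.00e-04, the smallest these draws can give. With matching on GC content as well, the share was 18.0%. That GC content was of the longest transcript, so the base composition of the 3' UTR itself was not matched, nor was expression level. The draws compare genes and do not measure the spread between libraries. Among genes that rose, 15 of 230 (6.52%) had an element against 13.4% of matched genes (matched-draw p of 0.0013). The matched share was 9.88% when also matched on GC content (matched-draw p of 0.069). With no excess, the tables argue against an element in the 3' UTR as the general source of the increases. They do not exclude it for the 15 genes that had one, and sites outside the 3' UTR were not searched. With the GC trend of each library removed, the medians of the genes that fell and rose were -0.94 and 0.97, and 155 and 144 of them still passed limma. These genes had been called on the uncorrected values, each with a change of at least 0.504 log2 units. Only an average trend was removed, so its removal could hardly cancel such changes. Whether GC content contributed to them cannot be decided this way. The trend itself (Spearman 0.252 of log2 fold change on transcript GC, across genes, which are not independent replicates) was 0.249 between the control libraries (replicate 1 minus 2) and -0.136 between the Qk_KO libraries, and an indirect route to the decreases without an element, as for Vcam1, Hmox1 and Gatm, stays open.

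The neuron list lay higher in Qk_KO, a camera call that was lost with an estimated correlation (adjusted p = 0.745 in limma with Benjamini-Hochberg adjustment, and 0.375 by fry). Without Qk_KO replicate 1 the list's median log2 fold change was 0.64, so the shift was not confined to that library, though 1 Qk_KO library remained. With the GC trend removed the median was 0.48, against 0.50 before (camera in limma with the preset correlation, Benjamini-Hochberg adjusted p = 0.00248). The average GC trend thus accounted for little of the median. That p does not measure the spread between libraries, and a part for GC content beyond the average trend stays open. Weaker repression by REST, which silences neuronal genes outside neurons, is a candidate explanation, and a list of 46 genes it represses, 45 of them tested, had a median of 0.89, above all of 10000 random lists matched on mean TPM (percentile 100), with 11 genes called higher and 0 lower. That list was drawn up after calls had been seen and 10 of its genes are also in the neuron list, while the other 24 genes of the neuron list had a lower median of 0.40, also high among random lists (percentile 99.99). The difference between these medians was not tested and the list held genes already known to be called, so a REST effect cannot be told apart from a rise of neuronal transcripts in general, and Stmn2 and Syt4 of the list had log2 fold changes of -0.37 and -0.24 and Rest was at 7.08 and 7.01 TPM in control and 7.67 and 7.15 TPM in Qk_KO.

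In Qk_KO replicate 1 the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were at 35.4, 19.1, 14.3 and 6.81 TPM and at most 0.01 TPM elsewhere, and Xist was at 0.04 TPM against 57.6 to 62.5 TPM, which is consistent with cells of a male embryo in that library and of female embryos in the others. In the same library Dlx2, Dlx1 and Six3, genes of the ventral forebrain, stood at 76.0, 36.7 and 30.8 TPM, against at most 2.60, 2.03 and 1.10 TPM elsewhere. A list of 12 markers of ganglionic eminence neurons, 5 of them shared with the neuron list, had a median of 0.94 TPM there, 1.67% of the mean of Dlx1 and Dlx2. The median was 0.19 to 0.45 TPM in the other libraries, and the highest member, Npy, was at 24.8 TPM there and 17.8 to 28.6 TPM elsewhere. This median cannot decide how much of the Dlx1 and Dlx2 signal came from such neurons, because different genes need not have like TPM in 1 cell type. Gad2 of the list was at 1.41 TPM against at most 0.38 TPM. Gad1 and Sp9 outside the list were at 20.7 and 7.16 TPM against 2.16 to 7.44 and at most 0.61 TPM, so such neurons stay open as a source. Sex cannot be told apart from other properties of the library because 1 library was male, and ventral progenitors without these markers stay open and untested.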
